A study of Mus musculus with 12 samples.

How the data were processed

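Total RNA was measured in mammospheres, the floating spheres that mammary epithelial cells form in suspension culture, grown from C57BL/6J mice that were wild type (WT) or lacked p66Shc (KO). Per the labels' protocols, mammospheres at passage 2 came from mice of 2 and of 12 months, RNA was isolated with the PicoPure kit and libraries were made with the TruSeq Stranded total RNA kit. The 12 libraries fell into 4 groups of 3, named here by genotype, age and replicate number. The labels do not state whether each library came from a separate animal and culture, so every p-value here measures the spread between these libraries.

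Per the submitters' processing notes, reads were mapped to mm10 with TopHat2 2.1.0 and Bowtie2 2.2.4, handled with SAMtools 0.1.18 and counted per gene with HTSeq 0.6.1p1. The gene annotation, the strand setting of the counting and the handling of multiply mapped reads are not given in the sources used here. The deposited signal values are CPM (read counts relative to library size) scaled by trimmed mean of M-values (TMM) in edgeR, per the file headers. The deposited table holds 23406 genes by 12 libraries, with 47 genes of chromosome Y, no gene of the mitochondrial chromosome and 3758 genes without a read in any library. Its columns sum to between 911481.5 and 1056325.8, as CPM divided by TMM-scaled library sizes do.

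Whole reads were recovered by dividing each deposited CPM value by the CPM of 1 read in its library. In every library 100% of the values above 0 lay within 0.1 of a whole number of reads. The recovered totals ran from 31845169 to 109079737 reads per library. A count of 3 reads, used as the floor, stood for 0.029 to 0.0859 CPM. Intervals and floors cover counting error only.

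The recovered totals allowed the deposited TMM factors to be compared with factors from edgeR runs on each of the 15 subsets of the 4 groups. Within 5e-04 log2, the factors of the 12-month WT libraries equalled those of a run on the 12-month WT and KO libraries alone. Those of both KO groups equalled a run on the 6 KO libraries alone, and those of the 2-month WT libraries matched no subset. The columns therefore do not share 1 scale, and the age comparison in KO is the one comparison between groups scaled in a single run. TMM recomputed over all 12 libraries changed the library size of 2-month WT by a mean of 0.0588 log2, of 12-month WT by -0.0037, of 2-month KO by -0.0296 and of 12-month KO by -0.0255. This recomputation was chosen after seeing the data, and its counts of changed genes stand beside the main ones.

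The tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise. The fixed design named a test for RPKM, FPKM and TPM but not for CPM, and that test was used. Values were taken as log2(CPM + 0.5) for the 13961 genes with a mean of at least 0.5 CPM over the 12 libraries. Fold changes on this scale understate those of genes with few reads. A linear model of the 4 groups was fitted to all 12 libraries in limma 3.58.1 (R 4.3.3) with a mean-variance trend and 8 residual degrees of freedom. It gave 5 comparisons, namely age in WT, age in KO, genotype at 2 months, genotype at 12 months, and the age by genotype interaction. The interaction is the age effect in KO minus that in WT. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene counted as changed at an adjusted p under 0.05.

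Of 41 gene lists fixed in advance, 39 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data. The lists of mitochondrially encoded and erythrocyte genes were not tested. The rotation test fry was also run; it asks whether the genes of a set move, on balance, one way. Called lists numbered 20, 21, 13, 17 and 17 of 39 in the 5 comparisons with the preset correlation, 4, 0, 0, 0 and 0 with the estimated one, and 29, 35, 25, 34 and 30 with fry. The lowest adjusted p with an estimated correlation was 0.0272, 0.11, 0.202, 0.152 and 0.155. Counts of a called list's genes are over all genes tested, and where no second count is given the count adjusted over the list alone was the same. Adjusted p-values of lists are from camera with the preset correlation unless the estimated one is named.

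The text names genes by a fixed rule among those with an adjusted p under 0.05. These are the 10 with the largest rise and the 10 with the largest fall in each comparison, leaving out predicted genes, and up to 4 members per list in the list's direction with the smallest p. Shc1, Insc, Trp53, Numb, Gpsm2, Cdkn1a, Mdm2, Myc and Mki67 are given whatever their result. Some genes that the rule allows are left out. Gene coordinates and strands are those deposited with the values. Transcript lengths and GC content are from GENCODE vM21 on GRCm38, which is mm10, and are those of the longest transcript of each symbol. Of the 23406 symbols, 98.47% matched it, 21775 directly and 1274 as synonyms.

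Count-based tests were run on the recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. edgeR called 7734, 9367, 1426, 9741 and 8018 genes in the 5 comparisons, and DESeq2 called 7749, 9339, 1727, 9757 and 8085. Other alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 2 CPM, median-of-ratios and quantile scaling, no trend, sample weights, fits on 2 groups alone, the replicate number as a block, and leaving out each library in turn.

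The fit was tested on simulated counts with the means and depths of these libraries for the age comparison in WT, over 13961 genes. limma recovered 9 of 50 genes changed 1.25-fold, 39 of 50 changed 1.5-fold, 48 of 50 changed 2-fold and 50 of 50 changed 4-fold. Of its 185 calls, 5.41% fell on unchanged genes, and for edgeR 5.91% of 186 did. With 1 list planted, camera called 2 of 39. The simulation drew genes independently, changed few of them and scaled all libraries in 1 run. Its error rates therefore need not hold for the real libraries, where many genes changed and the columns do not share 1 scale. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.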

Results

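Gene expression was profiled by RNA sequencing of total RNA in 12 libraries of mouse mammospheres at passage 2. The 4 groups of 3 libraries were WT and KO at 2 and at 12 months, where KO mice lacked p66Shc, the longest protein made from Shc1 and an adaptor linked to oxidative stress and lifespan. The series title places p66Shc together with p53 and Insc in the control of division mode and proliferation of mammary stem cells during ageing. Libraries held 31845169 to 109079737 reads in genes, with the highest total in replicate 3 of 12-month KO, and 17108 to 18025 genes with at least 1 read. Values are deposited CPM given as mean ± SD with n = 3 per group, and log2 fold changes are from limma with their SE.

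The matrix gene Thbs2 was the most abundant transcript, with a mean of 10883 CPM over the 12 libraries, followed by Spp1 with 10086, Ahnak with 6431 and Col4a1 with 5810. The group means of the fibroblast genes Col3a1 and Dcn were 2481 to 5045 and 1679 to 4137 CPM. The luminal keratin Krt8 and the epithelial adhesion gene Epcam were 505 and 407 CPM in 12-month WT, and 48.8 to 77.1 and 53.4 to 65.6 CPM in the other groups. The basal keratin Krt14 was 58.1 CPM in 12-month WT and 13.4 to 26.4 elsewhere, the skeletal muscle gene Ttn 145 to 1046 and the leukocyte gene Ptprc 19.6 to 32.4. The 10 most abundant genes took 5.92% to 7.70% of the deposited counts in each library.

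The first principal component carried 49.0% of the variance and the second 38.6%. On the first, 12-month WT libraries scored 57.4 to 59.9 and the 2-month libraries of both genotypes -36.5 to -30.1. On the second, 12-month KO libraries scored -59.8 to -55.8 and all other libraries were above 0. Replicates within a group correlated at 0.991 or more across genes, and edgeR's biological coefficient of variation was 0.0891.

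**Figure D1:**
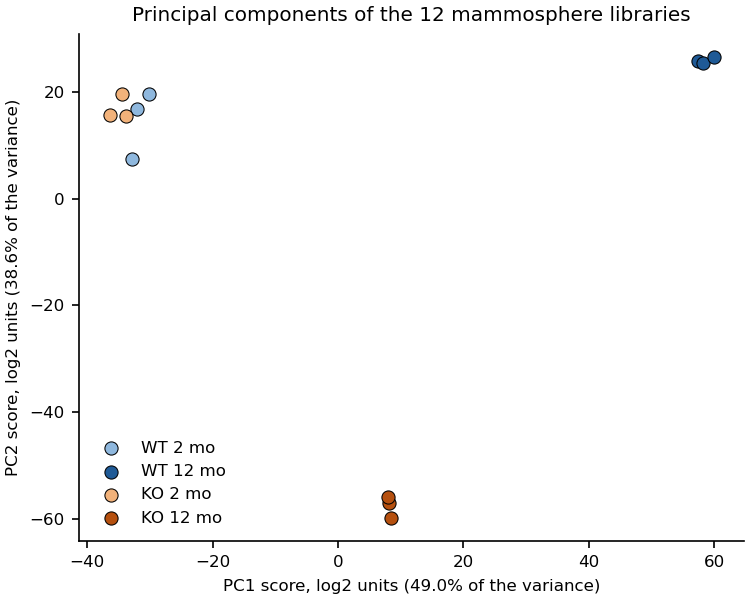
Scores of the 12 mammosphere libraries on the first (x axis, log2 units, 49.0% of the variance) and second (y axis, log2 units, 38.6%) principal components, 1 point per library, coloured by genotype and age. The 2-month WT and KO libraries lie together, while 12-month WT and 12-month KO lie apart from them and from each other.

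Shc1 was measured first, since the knockout removes 1 of its isoforms. Shc1 (chromosome 3, 89418550 to 89430029, plus strand) had 296 ± 25.3 CPM in 2-month WT, 211 ± 8.44 in 12-month WT, 208 ± 0.329 in 2-month KO and 170 ± 7.6 in 12-month KO. KO was lower than WT by a log2 fold change of -0.50 ± 0.06 at 2 months (adjusted p = 0.000133) and -0.31 ± 0.06 at 12 months (adjusted p = 0.000593). With age it fell by 0.49 in WT (adjusted p = 1.56e-05) and by 0.29 in KO (adjusted p = 0.000947). Because reads of all Shc1 isoforms are summed per gene, the level checks the labels only in part.

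Insc encodes Inscuteable, an adaptor that orients the mitotic spindle in asymmetric divisions. Insc (chromosome 7, 114745765 to 114850380, plus strand) had 15 to 41 reads per library outside 12-month KO and 2, 9 and 14 reads there, or 0.583 ± 0.0617 CPM in 2-month WT, 0.487 ± 0.109 in 12-month WT, 0.777 ± 0.119 in 2-month KO and 0.133 ± 0.081 in 12-month KO. Its mean of 0.495 CPM lay just under the filter, so it was tested only in the fit without a filter. There it fell with age in KO by 1.02 ± 0.11 log2 (adjusted p = 1.35e-05), and its change in WT of -0.14 did not pass (adjusted p = 0.362). KO was lower than WT at 12 months (-0.64, adjusted p = 0.000431) and not called at 2 months (0.24, adjusted p = 0.239). The interaction was -0.88 ± 0.16 (adjusted p = 0.000813). Exact two-sided permutation p-values for Insc were 0.4 and 0.1 for age in WT and KO, and 0.2 and 0.1 for genotype at 2 and 12 months, where 0.1 is the smallest that 3 against 3 libraries allow.

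Numb, a Notch antagonist that is partitioned unequally in asymmetric divisions, lies on chromosome 12 (83794033 to 83921934, minus strand). Numb rose with age in WT from 31.6 ± 1.81 to 47.7 ± 0.418 CPM (0.59 ± 0.06, adjusted p = 7.03e-07) and less in KO, from 29.2 ± 0.694 to 33.4 ± 0.579 CPM (0.19 ± 0.06, adjusted p = 0.00803). Between genotypes, Numb was lower in KO at 12 months (-0.51, adjusted p = 2.47e-06) and not called at 2 months (-0.11, adjusted p = 0.22). The interaction for Numb was -0.40 ± 0.08 (adjusted p = 0.000669). Gpsm2, which encodes the spindle-orientation protein LGN, fell by 0.95 in WT (adjusted p = 2.07e-07) and by 0.83 in KO (adjusted p = 7.8e-07), with no interaction call (0.12, adjusted p = 0.357). The fixed list of asymmetric division and polarity genes passed in none of the 5 comparisons. Of its 28 measured genes 9 rose and 6 fell with age in WT (adjusted p = 0.0605) and 8 rose and 9 fell in KO (adjusted p = 0.941). Between genotypes, 4 were lower in KO at 2 months (adjusted p = 0.952), while 8 were higher and 17 lower at 12 months (adjusted p = 0.103), and the interaction gave 0.0873. With age in WT it was called without replicate 2 of 2-month WT (adjusted p = 0.0194) or replicate 1 of 12-month WT (0.0425), and the interaction without replicate 2 of 2-month WT (0.0461). Quantile scaling called it in these comparisons and at 12 months (adjusted p = 0.00721 to 0.0142). It was also called with no filter at 12 months (adjusted p = 0.0412) and in the interaction (0.0346). A filter at a mean of 2 CPM called it with age in WT (0.0453).

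The proliferation marker Mki67 fell with age from 401 ± 43.2 to 137 ± 4.69 CPM in WT (-1.54 ± 0.12, adjusted p = 1.38e-07) and from 380 ± 32.9 to 169 ± 32.9 CPM in KO (-1.18 ± 0.12, adjusted p = 1.81e-06). Its interaction was 0.36 (adjusted p = 0.0919), and KO and WT did not differ by the test at 2 months (-0.08, adjusted p = 0.744) or 12 months (0.28, adjusted p = 0.0534; 0.30 and 0.0423 with TMM over all 12 libraries). In 12-month KO, Mki67 was 184.5, 191.3 and 131.1 CPM in replicates 1 to 3, against 133 to 142.2 in 12-month WT, so replicate 3 stood apart. Myc rose with age in KO from 11.7 to 29.0 CPM (1.27 ± 0.12, adjusted p = 6.9e-07) and in WT from 11.9 to 14.6 CPM (0.30 ± 0.12, adjusted p = 0.0449). The WT call of Myc was lost in 11 alternative settings. Myc was higher in KO at 12 months (0.95, adjusted p = 9.2e-06) and not called at 2 months (-0.01, adjusted p = 0.964). The Myc interaction was 0.97 ± 0.17 (adjusted p = 0.000265). Trp53 was 17.5, 14.8, 14.3 and 13.3 CPM in 2-month WT, 12-month WT, 2-month KO and 12-month KO. Its fall with age in WT (-0.23, adjusted p = 0.0193) and lower level in 2-month KO than WT (-0.28, adjusted p = 0.0249) both lost the call with TMM over all 12 libraries, at adjusted p of 0.0759 and 0.146. The p53 target Cdkn1a was 172, 159, 154 and 163 CPM in the same order and was called in no comparison, with an interaction of 0.19 (adjusted p = 0.0929). Mdm2, which encodes the ligase that degrades p53, fell with age by 0.44 in WT (adjusted p = 0.00189) and by 0.49 in KO (adjusted p = 0.000769). Mdm2 was not called between genotypes at 2 months (-0.22, adjusted p = 0.176) and was called lower in KO at 12 months (-0.26, adjusted p = 0.032), a call that the fit without a filter lost (adjusted p = 0.0527).

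**Figure D2:**
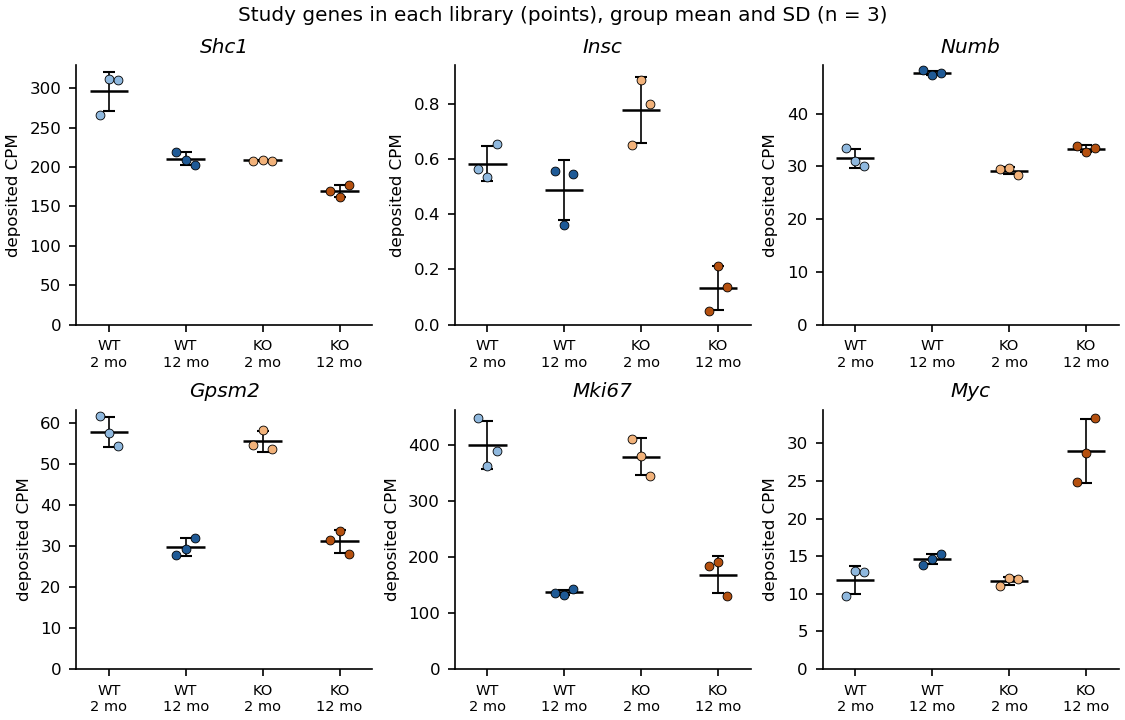
Deposited CPM (y axis) of Shc1, Insc, Numb, Gpsm2, Mki67 and Myc in each library of the 4 groups (x axis), with points for the 3 libraries, a line for the mean and a bar for the SD. Mki67 was 401 and 380 CPM in the 2-month WT and KO groups and 137 and 169 CPM in the 12-month ones.

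With age in WT mammospheres, genes of luminal epithelium rose and genes of cell division, fibroblasts and skeletal muscle fell. The luminal keratin Krt18 (chromosome 15, 102028215 to 102032026, plus strand) rose from 93.2 ± 8.64 to 1150 ± 86.5 CPM (3.62 ± 0.08, adjusted p = 1.63e-12). Mitotic topoisomerase Top2a fell from 563 to 175 CPM (-1.69 ± 0.09, adjusted p = 1.8e-09). All 18 genes of the luminal keratin and claudin list rose, with a median of 3.30 (adjusted p = 4.61e-18; 0.0277 with an estimated correlation), and all 43 G2/M genes fell, with a median of -1.52 (adjusted p = 3.18e-18; 0.191 with an estimated correlation). The comparison asks what ageing does to cells that have p66Shc.

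Of 13961 genes, 8091 changed with age in WT, 3120 higher and 4971 lower, so that 38.56% of calls were rises. With TMM recomputed over all 12 libraries 7727 of 13957 genes changed, 3585 higher and 4142 lower (46.4% rises). It kept 89.75% of the calls and reversed 0 of them. Rises of more than 1 log2 numbered 989 and falls 738. Over all genes tested, the 3 libraries of one age did not overlap those of the other in 62.25%, where chance gives 10%.

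Fcgbp, which encodes a mucus protein, rose from 2.18 ± 0.547 to 123 ± 10.8 CPM (5.55 ± 0.18, adjusted p = 1.96e-11; chromosome 7, 28071235 to 28120864, plus strand). Tfcp2l1, which encodes an epithelial transcription factor, went from 4.84 ± 0.278 to 184 ± 0.152 CPM (5.11 ± 0.09, adjusted p = 5.25e-13; chromosome 1, 118627944 to 118685168, plus strand). The sodium channel subunit Scnn1a rose by 4.88 ± 0.16 (adjusted p = 2.26e-11), the luminal surface gene Ly6d by 4.85 ± 0.18 (adjusted p = 7.6e-11) and the monocarboxylate transporter Slc5a8 by 4.81 ± 0.10 (adjusted p = 1.35e-12). Cited4, Klhdc7a, Myh14 and Gjb2 rose by 4.78, 4.66, 4.61 and 4.38. Ehf, an ETS factor of epithelia, rose from 15.9 ± 1.09 to 340 ± 5.54 CPM (4.38 ± 0.10, adjusted p = 1.63e-12; chromosome 2, 103263432 to 103303196, minus strand). Among other luminal genes, Krt8 rose by 3.38, Krt7 by 2.99, the surface marker Cd24a by 3.20 (32.6 to 302 CPM) and the claudin Cldn4 by 3.51 (76.9 to 868 CPM).

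In the luminal progenitor list 22 of 23 genes rose, with a median of 2.59 (adjusted p = 8.33e-17; 0.0272 with an estimated correlation), among them the progenitor factor Elf5 (4.25 ± 0.12, 2.11 to 49.0 CPM), the receptor Kit (2.86 ± 0.07, 11.1 to 83.6 CPM), the milk-protein gene Ltf (4.28 ± 0.13, 26.1 to 513 CPM) and Lcn2 (119 to 1292 CPM). Other lists hold 11 of the luminal progenitor genes. In the hormone-sensing luminal list 18 of 25 rose and 3 fell, with a median of 1.16 (adjusted p = 2.71e-08; 0.0272 with an estimated correlation). In the keratinisation list 8 of 12 rose and 2 fell, with a median of 1.91 (adjusted p = 0.000319; 0.0301 with an estimated correlation). These 4 lists were the ones still called with an estimated correlation. The basal list had 16 rises and 8 falls among 28 genes (adjusted p = 0.00147; 0.169 with an estimated correlation), with Krt5 up from 0.767 to 10.8 CPM and the basement-membrane gene Lamb3 up from 16.8 to 125 CPM. The NF-kB list had 20 rises and 6 falls among 32 (median 0.43, adjusted p = 8.1e-05; 0.179 with an estimated correlation), and the Hippo target list had 14 rises and 5 falls among 24 (median 0.27, adjusted p = 0.000962; 0.169 with an estimated correlation), with Ctgf up from 147 to 506 CPM. Adjusted over the list alone, the basal list had 18 rises and 8 falls, and the counts of the other lists in this paragraph were the same.

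Division genes fell together. All 40 G1/S genes fell, with a median of -1.14 (adjusted p = 9.91e-16; 0.154 with an estimated correlation), including the replication factor Mcm10 (-1.56), the ribonucleotide reductase Rrm2 (-1.52) and the methylation adaptor Uhrf1 (-1.44, 97.9 to 35.8 CPM). The kinetochore histone Cenpa fell by 1.53 ± 0.07 (adjusted p = 6.21e-10) and Birc5, which encodes survivin, fell with it. In the DNA repair list 28 of 44 fell and 5 rose (29 and 5 adjusted over the list alone), with a median of -0.36 (adjusted p = 0.0011; 0.225 with an estimated correlation), and Brca1 fell from 70.4 to 26.3 CPM. Of 30 histone genes 17 fell (19 adjusted over the list alone) and 0 rose, with a median of -0.90 (adjusted p = 0.00804; 0.683 with an estimated correlation). Replicate 1 of 2-month WT lay at -0.72 on the mean of this list, relative to the 2-month WT mean, against 0.35 and 0.37 for its replicates and -0.97 to -0.66 in 12-month WT, and without it the median change was -1.29.

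Mesenchymal and muscle genes were lower in 12-month WT. The mesenchymal factors Zeb1 (152 to 60.2 CPM, -1.32 ± 0.07, adjusted p = 2.15e-09), Snai2 (-1.27) and Twist1 (-1.08) fell, as did 20 of 27 genes of the EMT list (21 adjusted over the list alone), with a median of -0.59 (adjusted p = 0.000873; 0.174 with an estimated correlation). The small leucine-rich proteoglycan genes Lum and Dcn fell from 502 to 158 CPM and from 3340 to 1679 CPM, and 15 of 19 fibroblast genes fell (adjusted p = 0.00212; 0.179 with an estimated correlation). All 11 skeletal muscle genes fell, with a median of -2.38 (adjusted p = 4.82e-06; 0.214 with an estimated correlation), and the embryonic myosin gene Myh3 went from 61.9 ± 7.63 to 5.69 ± 0.349 CPM (-3.33 ± 0.20, adjusted p = 1.03e-08; chromosome 11, 67078299 to 67102291, plus strand). Agtr2, the angiotensin type 2 receptor gene, fell from 238 ± 30.9 to 28.0 ± 5.88 CPM (-3.08 ± 0.23, adjusted p = 6.85e-08). Sterol synthesis genes fell in 19 of 24 cases (median -0.49, adjusted p = 0.000122; 0.179 with an estimated correlation), with Insig1 down from 501 to 244 CPM. Interferon-response genes fell in 24 of 43 (25 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.0234; 0.607 with an estimated correlation). That call was lost without replicate 3 of 2-month WT (adjusted p = 0.0638) or replicate 1 of 12-month WT (adjusted p = 0.067).

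With age in KO mammospheres, genes of inflammation and interferon response rose while histone, ribosomal protein and respiratory chain genes fell. Cxcl1 (chromosome 5, 90891244 to 90893115, plus strand), which encodes a neutrophil-attracting chemokine, rose from 9.01 ± 0.72 to 363 ± 39.2 CPM (5.26 ± 0.10, adjusted p = 7.37e-13). Of 32 NF-kB genes 31 rose and 0 fell, with a median of 1.74 (adjusted p = 6.74e-15; 0.11 with an estimated correlation). In the interferon list 41 of 43 rose (42 adjusted over the list alone) and 0 fell, with a median of 1.19 (adjusted p = 2.95e-14; 0.14 with an estimated correlation). The luminal keratin and claudin list was not called (10 rises and 2 falls of 18, median 0.44, adjusted p = 0.063; 0.0404 without replicate 3 of 2-month KO, 0.0287 without replicate 3 of 12-month KO and 0.0376 with no filter), and Krt18 was 135 ± 11.7 CPM at 2 months and 119 ± 2.64 CPM at 12 months. The comparison asks which age changes occur without p66Shc.

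Of 13961 genes, 9358 changed with age in KO, 4589 higher and 4769 lower, and 9380 of 13957 changed with TMM recomputed over all 12 libraries. Rises of more than 1 log2 numbered 1111 and falls 809. Over all genes tested, 72.93% had libraries that did not overlap between the ages, where chance gives 10%.

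The pentraxin Ptx3 rose from 10.3 ± 0.0311 to 499 ± 51.2 CPM (5.52 ± 0.08, adjusted p = 6.74e-14; chromosome 3, 66219886 to 66225806, plus strand). On chromosome 5, Cxcl5 rose to 61.6 CPM (5.18 ± 0.17, adjusted p = 4.27e-11) and Cxcl2 from 2.90 ± 0.238 to 79.8 ± 3.72 CPM (4.56 ± 0.09, adjusted p = 8.21e-13). The protease inhibitors Serpinb2 and Serpina3m rose by 4.49 and 4.26, complement C4b by 4.04 (11.8 to 203 CPM) and the chemoattractant Rarres2 by 4.06 (4.85 to 90.0 CPM). The acute-phase gene Saa3 rose from 139 to 812 CPM and the NF-kB regulator Nfkbiz from 40.3 to 273 CPM. The guanylate-binding gene Gbp2 rose by 2.14 ± 0.06 (28.3 to 126 CPM, adjusted p = 1.58e-11), the nucleic-acid sensor genes Zbp1 and Ifih1 by 2.82 and 1.43. In the senescence-associated secretory list 25 of 42 rose and 12 fell, with a median of 0.55 (adjusted p = 0.00413; 0.195 with an estimated correlation), and other lists hold 20 of its genes.

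Immediate-early, glycolytic and endothelial genes also rose. The AP-1 and immediate-early list had 22 rises and 2 falls among 28 (median 1.35, adjusted p = 2.14e-07; 0.14 with an estimated correlation), with the nuclear receptor Nr4a1 up by 4.01 ± 0.12 and Klf4 up from 10.2 to 98.4 CPM. Glycolysis and hypoxia genes rose in 22 of 31 cases (median 0.44, adjusted p = 3.2e-05; 0.288 with an estimated correlation), including adrenomedullin Adm (13.7 to 118 CPM) and Hk2 (1.57). Of 15 endothelial genes 14 rose and 1 fell, with a median of 1.89 (adjusted p = 1.41e-06; 0.14 with an estimated correlation), and the endothelial adhesion genes Pecam1 and Cdh5 rose from 18.7 to 98.1 and from 9.60 to 60.3 CPM. The luminal progenitor list rose in 16 of 23 (median 1.01, adjusted p = 0.000575; 0.155 with an estimated correlation), with Kit up by 3.58 ± 0.07 and Ehf by 1.80 ± 0.10. The stem and progenitor surface gene Ly6a, also interferon-induced, rose from 16.6 to 271 CPM (3.98 ± 0.09, adjusted p = 1.46e-12). Adjusted over the list alone, counts were the same for these lists except that the progenitor list had 4 falls in place of 3.

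Division genes fell in KO as in WT. All 43 G2/M genes fell (median -1.58, adjusted p = 1.81e-19; 0.184 with an estimated correlation) and all 40 G1/S genes (median -1.02, adjusted p = 1.46e-15; 0.14 with an estimated correlation), with Cenpa down from 45.4 to 9.70 CPM (-2.17 ± 0.07, adjusted p = 3.95e-11). Histone genes fell in 27 of 30 cases and rose in 1, with a median of -2.13 (adjusted p = 2.14e-07; 0.383 with an estimated correlation), and linker histone Hist1h1b fell from 55.9 to 8.04 CPM (-2.73 ± 0.16, adjusted p = 7.63e-09). Reads of histone genes can be shared between near-identical copies. Respiratory chain genes fell in 43 of 51 cases (median -0.39, adjusted p = 5.13e-07; 0.268 with an estimated correlation), among them the ATP synthase subunit Atp5o (66.9 to 37.2 CPM). Ribosomal protein genes fell in 46 of 73 cases (44 adjusted over the list alone), with a median of -0.58 (adjusted p = 1.23e-05; 0.366 with an estimated correlation), and Rps3 went from 1075 to 775 CPM. On the mean of the ribosomal protein list, replicate 3 of 12-month KO lay at -0.42 and the others at -0.87 and -0.82, relative to 2-month WT, and without it the median change was -0.73.

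Single genes with large falls included Agtr2, from 312 ± 20.1 to 3.33 ± 1.62 CPM (-6.43 ± 0.23, adjusted p = 8.01e-11; chromosome X, 21484623 to 21488833, plus strand), and the kappa-casein gene Csn3, from 33.3 ± 0.404 to 0.583 ± 0.224 CPM (-4.98 ± 0.11, adjusted p = 2.43e-12; chromosome 5, 87925632 to 87932264, plus strand). In WT, Csn3 went the other way, from 34.7 to 120 CPM. The macrophage scavenger receptor Marco fell from 31.1 to 1.23 CPM and the regeneration-related gene Nrep from 644 to 39.0 CPM. Fibrillar collagen Col3a1 fell from 5045 to 2481 CPM, and the p53-induced Pmaip1 from 187 to 56.4 CPM. The p53 target list was called in neither age comparison. In WT 10 of its 37 genes rose and 11 fell, with a median of -0.02 beside a mean of 0.18 and an upward test (adjusted p = 0.435), and in KO 11 rose and 17 fell (median -0.05, adjusted p = 0.335).

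**Figure D3:**
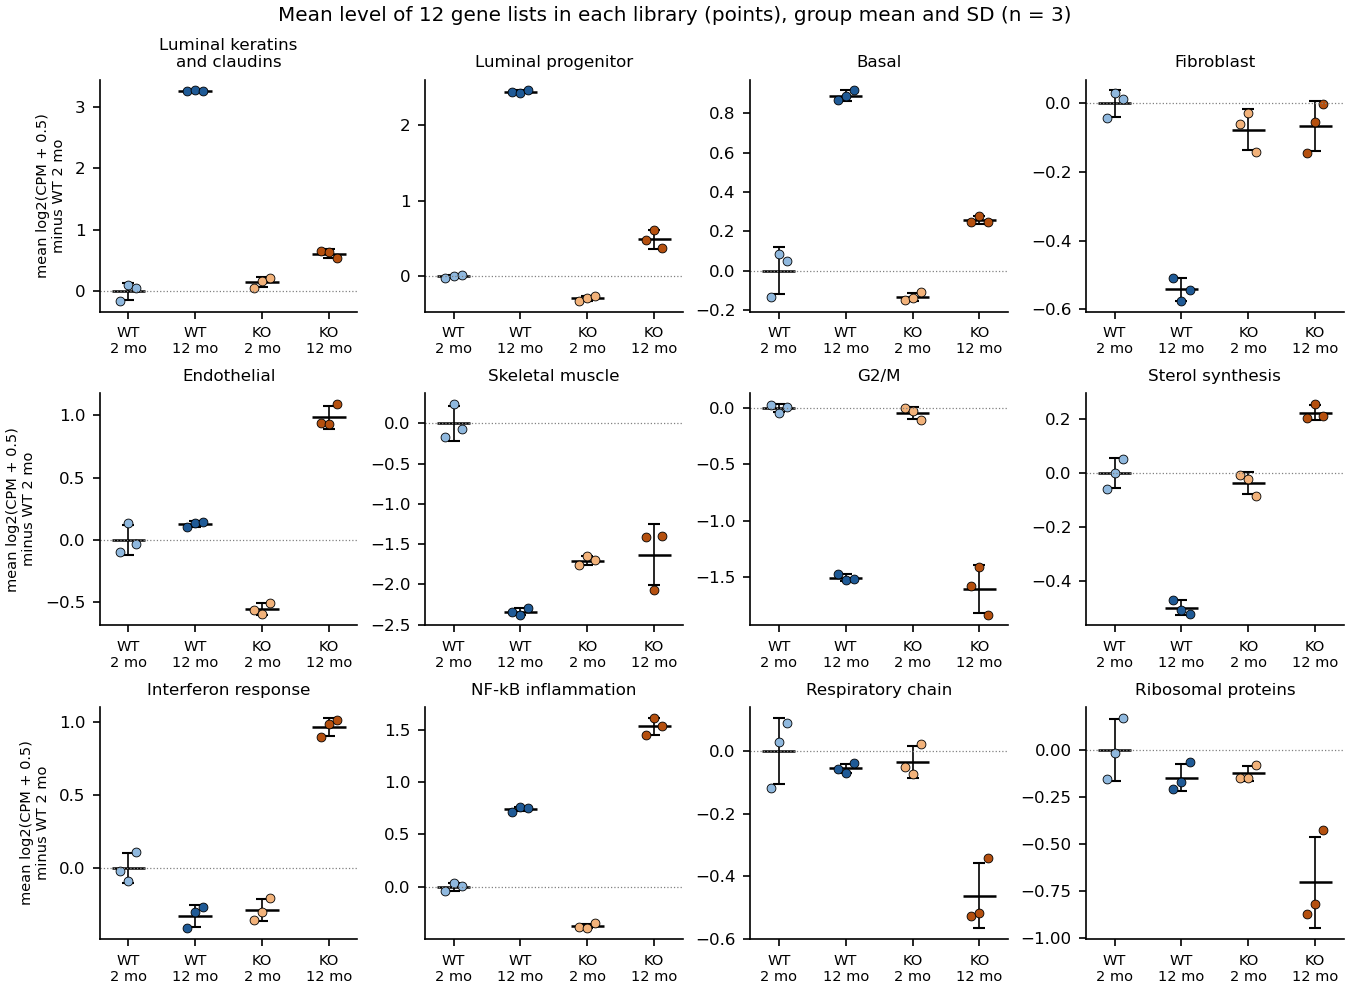
Mean log2(CPM + 0.5) of 12 gene lists in each library, minus the mean of 2-month WT (y axis, log2 units), for the 4 groups (x axis), with points for libraries, a line for the group mean and a bar for the SD (n = 3). The luminal keratin and claudin list stands apart in 12-month WT, and the NF-kB and interferon lists in 12-month KO.

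Between genotypes at 2 months, endothelial, muscle and inflammatory genes were lower in KO, and some of the largest differences lay near Shc1 on chromosome 3. The comparison asks what loss of p66Shc changes in mammospheres of young mice. Crct1 (chromosome 3, 93014204 to 93015686, minus strand), a gene of the epidermal differentiation complex, was 22.02 ± 1.76 CPM in WT and 1.07 ± 0.127 in KO (-3.84 ± 0.09, adjusted p = 6.7e-11). Pecam1 was lower by -0.93 ± 0.07 (adjusted p = 3.14e-06), as were 11 of 15 endothelial genes (13 adjusted over the list alone), with a median of -0.60 (adjusted p = 6.08e-06; 0.202 with an estimated correlation).

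Of 13961 genes, 2245 differed, 259 higher and 1986 lower in KO, and this split depended on the scaling. Rises made up 11.54% of the calls on the deposited scale, 29.3% with TMM over all 12 libraries (1454 genes, 426 higher and 1028 lower), 30.25% with median-of-ratios scaling, 39.56% with quantile scaling, 28.82% with edgeR and 30.63% with DESeq2. TMM over all 12 libraries kept 57.33% of the calls and reversed 0. Without replicate 1 of 2-month KO 1407 genes were called, and without its replicate 3 1493. The median of all genes was -0.0877 on the deposited scale and 0.0226 with quantile scaling, so small differences of either sign are relative to the scale used. Differences of more than 1 log2 numbered 14 higher and 178 lower. Over all genes tested, 32.1% had libraries that did not overlap between the genotypes, where chance gives 10%.

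Genes higher in 2-month KO included several on chromosome 3. The RNA-binding gene Rbm46 (82837232 to 82876483, minus strand) was 1.77 ± 0.605 CPM in WT and 14.9 ± 0.27 in KO (2.80 ± 0.19, adjusted p = 9.23e-07). The chitinase-like Chi3l3, on the same chromosome at 106147553 to 106167564, was 4.77 and 23.4 CPM (2.18 ± 0.10, adjusted p = 2.32e-08). Butyrylcholinesterase Bche (73635808 to 73708415, minus strand) was 30.2 and 94.0 CPM (1.62 ± 0.09, adjusted p = 1.59e-07). The antigen-presenting Cd1d2, which has a close paralog, was 0.043 and 1.43 CPM. Elsewhere, arginase Arg1 was higher by 1.19 ± 0.11 (adjusted p = 1.77e-05) and Col14a1 by 1.16 ± 0.12 (adjusted p = 4.25e-05). The matrix gene Postn was 1374 CPM in WT and 2749 in KO (adjusted p = 1.2e-05). The extracellular matrix list was called upward relative to other genes (adjusted p = 2.88e-07, or 0.3 with an estimated correlation, and not called by fry at 0.11). Its median was only 0.03, beside -0.0877 for all genes. In it 10 of 40 genes were higher and 4 lower (11 and 4 adjusted over the list alone). Krt18 and Krt8 were higher by 0.53 and 0.67, and the luminal keratin and claudin list had 5 genes higher (7 adjusted over the list alone) and a median of 0.12, or 0.18 without replicate 1 of KO (adjusted p = 1.83e-06; 0.215 with an estimated correlation, and not called by fry at 0.0714).

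Among genes lower in 2-month KO, Rps3a1 (chromosome 3, 86137939 to 86142668, minus strand) was 82.4 ± 46.0 CPM in WT and 1.31 ± 0.173 in KO (-5.38 ± 0.39, adjusted p = 1.63e-06). Histone gene Hist1h4m was 20.3 ± 8.89 and 0.0617 CPM, the latter from 8 reads in 3 libraries. Both have near-identical copies whose reads the counting could have divided. Cd5l, a macrophage-secreted protein gene on chromosome 3 (87357880 to 87371074, plus strand), was 18.4 and 1.23 CPM (-3.45 ± 0.13, adjusted p = 7.32e-09), and involucrin Ivl (92570899 to 92573735, minus strand) was 86.6 ± 1.05 and 20.02 ± 1.46 CPM (-2.09 ± 0.12, adjusted p = 1.59e-07). The mast-cell protease genes Mcpt4 and Cma1 were lower by -2.63 and -2.08. All 11 skeletal muscle genes were lower, with a median of -1.67 (adjusted p = 5.34e-14; 0.202 with an estimated correlation), and Myh3 and Myh1 went from 61.9 to 8.84 and from 41.1 to 6.85 CPM. Complement C3 was 190 CPM in WT and 54.7 in KO (-1.78 ± 0.08, adjusted p = 2.78e-08). The NF-kB list had 15 of 32 genes lower (19 adjusted over the list alone) and 1 higher, with a median of -0.28 (adjusted p = 6.08e-06; 0.215 with an estimated correlation), including Cxcl5 (-1.52) and Cxcl1 (-0.84). The interferon list had 21 of 43 lower (27 adjusted over the list alone), with a median of -0.29 (adjusted p = 1.85e-05; 0.531 with an estimated correlation), and H2-K1 was 380.5 CPM in WT and 264 in KO. Glycolysis genes were lower in 17 of 31 cases (22 adjusted over the list alone; median -0.29, adjusted p = 3.12e-06; 0.391 with an estimated correlation), with Bnip3 at -0.63 and Pdk1 at -0.50.

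Division genes differed little between the genotypes at 2 months. The G2/M list was not called (median -0.03, adjusted p = 0.12; 0.0355 without replicate 1 of WT and 0.0197 without replicate 3 of KO), and limma called 0 of its 43 genes, with 0 at an unadjusted p under 0.05 and 0 by edgeR or DESeq2. The histone list was called higher (median 0.06, adjusted p = 0.000691; 0.728 with an estimated correlation), while limma called 0 of its 30 genes, again with 0 at an unadjusted p under 0.05 and 0 by edgeR or DESeq2. The G1/S list was called lower (median -0.16, 6 genes lower or 8 adjusted over the list alone, adjusted p = 0.042; 0.728 with an estimated correlation). The median of the histone list was -0.25 without replicate 1 of WT (adjusted p = 0.697), -0.02 without replicate 3 of KO (adjusted p = 0.0446) and 0.18 to 0.25 without replicate 2 of KO or replicate 2 or 3 of WT. TMM over all 12 libraries gave adjusted p = 0.0514 for histones and 0.0781 for G1/S. An upward call by camera is relative to the other genes, and the median of all genes was -0.0877, so it need not mean higher in KO. The ribosome biogenesis list was called upward against a median of -0.01 (adjusted p = 0.042; 0.509 with an estimated correlation). The AP-1 list was also called upward, with a median of -0.02 beside a mean of 0.01 (adjusted p = 0.0235; 0.682 with an estimated correlation, and 0.0514 with TMM over all 12 libraries). The G1/S call was also lost without replicate 2 or 3 of WT or any 1 of the KO replicates, the ribosome biogenesis call without replicate 1 of WT or 3 of KO, and the AP-1 call without replicate 1 of WT or 2 of KO (adjusted p = 0.0532 to 0.276).

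**Figure D4:**
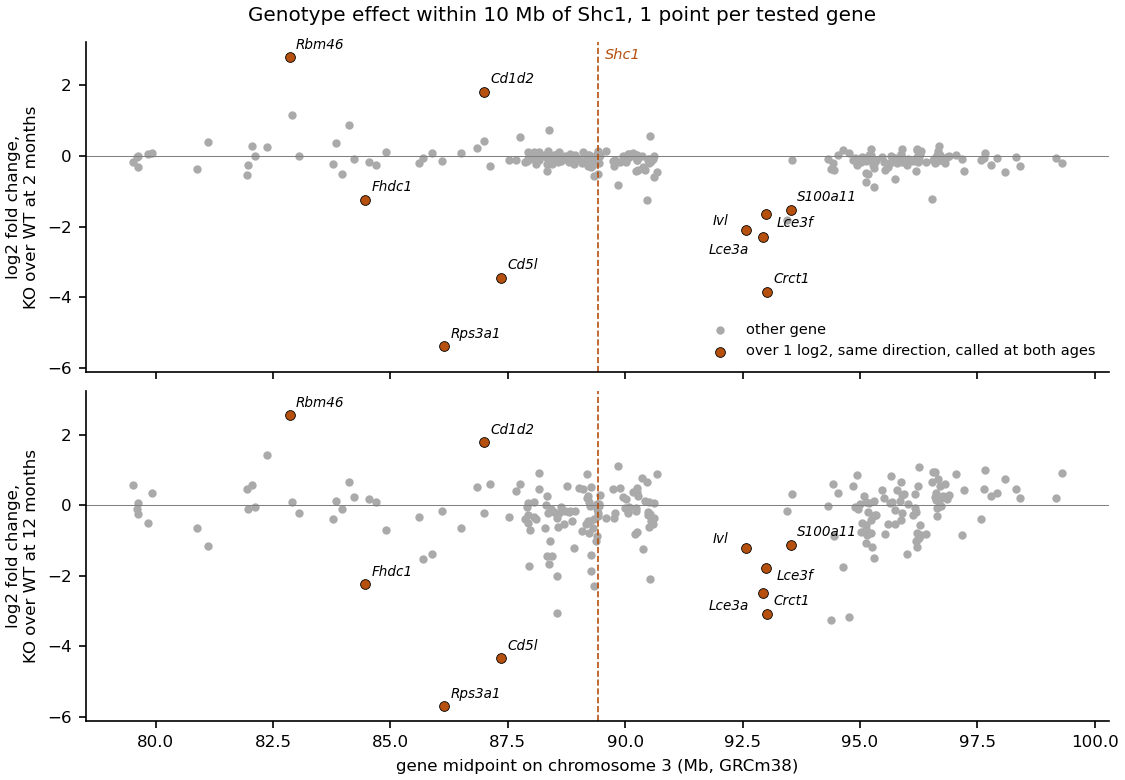
Log2 fold change of KO over WT (y axis) at 2 months and at 12 months (1 panel each) against position on chromosome 3 (x axis, Mb) for genes within 10 Mb of Shc1, 1 point per gene, with Shc1 at the dashed line. The 10 labelled genes differ in the same direction at both ages, from Rbm46 (2.80 at 2 months) to Rps3a1 (-5.38).

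Between genotypes at 12 months, luminal genes were lower in KO while interferon, NF-kB, immediate-early, sterol and mesenchymal genes were higher. Krt18 was 1150 ± 86.5 CPM in WT and 119 ± 2.64 in KO (-3.27 ± 0.08, adjusted p = 4.75e-12), and all 18 luminal keratin and claudin genes were lower, with a median of -2.77 (adjusted p = 2.67e-10; 0.152 with an estimated correlation). The antiviral gene Rsad2 was 13.0 and 84.3 CPM (2.65 ± 0.12, adjusted p = 3.22e-10), and 40 of 43 interferon genes were higher, with a median of 1.30 (adjusted p = 8.17e-14; 0.154 with an estimated correlation). The comparison asks what loss of p66Shc changes in mammospheres of older mice.

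Of 13961 genes, 9801 differed, 4372 higher and 5429 lower in KO, and 9755 of 13957 with TMM over all 12 libraries, 4534 higher and 5221 lower. Differences of more than 1 log2 numbered 931 higher and 1387 lower. The libraries of the genotypes did not overlap in 73.95% of all genes tested, where chance gives 10%.

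Fosb (chromosome 7, 19302695 to 19310045, minus strand), which encodes an AP-1 subunit, was 5.17 ± 0.788 CPM in WT and 109 ± 15.1 in KO (4.27 ± 0.17, adjusted p = 1.43e-10). Epiregulin Ereg (chromosome 5, 91074616 to 91093649, plus strand) was 8.48 and 144 ± 23.1 CPM (adjusted p = 1.12e-11). Nr4a1 was higher by 3.53 ± 0.12 (adjusted p = 5.59e-11), the endothelial shear factor Klf2 by 3.48 ± 0.11 (adjusted p = 2.57e-11) and the hyaluronan-binding Tnfaip6 by 3.41 ± 0.08 (19.1 to 208 CPM, adjusted p = 4.69e-12). Chl1, Mcpt4, Serpina3m and Kng1 were higher by 3.66, 3.61, 3.47 and 3.45. The mucin-type glycosyltransferase Galnt16 was 22.3 and 224 CPM (3.30 ± 0.06, adjusted p = 2.98e-13). In the AP-1 list 19 of 28 genes were higher and 5 lower (adjusted p = 2.87e-05; 0.27 with an estimated correlation), with Egr1 at 12.2 and 84.1 CPM. In the NF-kB list 22 of 32 were higher and 7 lower (median 1.03, adjusted p = 2.87e-05; 0.21 with an estimated correlation), with Saa3 at 152 and 812 CPM and Cxcl2 higher by 3.26 ± 0.09.

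Sterol synthesis genes were higher in 22 of 24 cases and lower in 0, with a median of 0.65 (adjusted p = 9.72e-08; 0.152 with an estimated correlation), including Stard4 (1.36) and Nsdhl (1.31). In the EMT list 19 of 27 were higher and 3 lower (median 0.65, adjusted p = 7.73e-05; 0.152 with an estimated correlation), with Zeb2 at 1.41 and fibronectin Fn1 at 1210 and 2796 CPM. Of 19 fibroblast genes 13 were higher and 6 lower (median 0.50, adjusted p = 0.0209; 0.332 with an estimated correlation), with the receptor Pdgfra at 390 and 951 CPM and Dcn higher by 1.30. Endothelial genes were higher in 12 of 15 cases (median 0.90, adjusted p = 0.000101; 0.154 with an estimated correlation), with the VEGF receptor Flt1 at 1.84. The unfolded protein response list had 20 of 32 higher and 8 lower (median 0.33, adjusted p = 0.0176; 0.27 with an estimated correlation). With quantile scaling this list and the fibroblast list were not called (adjusted p = 0.681 and 0.232). Counts adjusted over the list alone were the same for the lists of this and the previous paragraph.

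Among genes lower in 12-month KO, Csn3 had 120 ± 1.77 CPM in WT and 0.583 ± 0.224 in KO (-6.82 ± 0.11, adjusted p = 2.98e-13). Klhdc7a was 161 and 2.76 CPM (-5.65 ± 0.11, adjusted p = 9.95e-13), Fcgbp 123 and 5.88 CPM (-4.29 ± 0.18, adjusted p = 1.99e-10), Arg1 56.1 and 3.08 CPM (-3.99 ± 0.11, adjusted p = 1.12e-11) and the GABA receptor subunit Gabrp 34.0 and 1.70 CPM (-3.98 ± 0.16, adjusted p = 1.53e-10). The aldehyde dehydrogenase Aldh3a1 was 10.5 and 0.213 CPM (-3.95 ± 0.11, adjusted p = 1.39e-11). Hist1h4m was 11.9 ± 3.26 CPM in WT with 0 reads in the 3 KO libraries, where the floor of 3 reads per library stood for 0.029 to 0.0765 CPM, so it was at least 156-fold lower. Epcam was 407 and 60.7 CPM, Krt7 was lower by -3.65 ± 0.07 and Ehf by -2.74 ± 0.10. In the luminal progenitor list 19 of 23 were lower and 1 higher (median -1.84, adjusted p = 5.93e-07; 0.152 with an estimated correlation), and in the hormone-sensing list 15 of 25 were lower and 6 higher (median -0.52, adjusted p = 0.0277; 0.27 with an estimated correlation, and 0.0554 with a filter at a mean of 2 CPM). The polarity genes Crb3, Pard6b, Llgl2 and Prkcz were lower by -3.19, -2.68, -2.61 and -2.53.

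Respiratory chain genes were lower in 41 of 51 cases (median -0.35, adjusted p = 7.73e-05; 0.476 with an estimated correlation), with Atp5a1 at 802 CPM in WT and 560 in KO. Ribosomal protein genes were lower in 42 of 73 cases (38 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.00319; 0.57 with an estimated correlation). Histone genes were lower in 26 of 30 (median -1.02, adjusted p = 0.00825; 0.65 with an estimated correlation). The division lists did not pass, with 3 of 43 G2/M genes higher and 16 lower (median -0.13, adjusted p = 0.521) and 7 of 40 G1/S genes higher and 11 lower (median -0.05, adjusted p = 0.754), and without replicate 3 of KO these medians were 0.02 and 0.01. Of 37 p53 targets 8 were higher and 24 lower (median -0.28), which did not pass (adjusted p = 0.0819; 0.0399 without replicate 3 of WT, 0.0365 with no filter and 0.0121 with quantile scaling).

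The age effect itself differed between the genotypes in luminal, interferon, NF-kB, sterol and muscle genes. The luminal keratin Krt7 (chromosome 15, 101412402 to 101427806, plus strand) went from 43.0 to 344 CPM with age in WT and from 53.5 to 26.9 CPM in KO, an interaction of -3.96 ± 0.10 (adjusted p = 3.34e-11). All 18 luminal keratin and claudin genes had a negative interaction, with a median of -2.85 (adjusted p = 1.11e-13; 0.155 with an estimated correlation). In the interferon list 41 of 43 had a positive one, with a median of 1.58 (adjusted p = 8.9e-15; 0.155 with an estimated correlation). This comparison asks whether p66Shc alters how mammospheres change with age.

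The interaction was called for 8051 of 13961 genes, 4388 positive and 3663 negative, and for 8155 of 13957 with TMM over all 12 libraries, 3917 positive and 4238 negative. Absolute interactions above 1 log2 numbered 1344 positive and 1146 negative. Of the 8091 genes changed with age in WT, 3882 (47.98%) changed in the same direction in KO, 1824 (22.54%) in the opposite direction and 2385 (29.48%) were not called in KO. An interaction was called for 5334 of them (65.93%).

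Among genes known from mast cells, Mcpt4 had an interaction of 6.24 ± 0.19 (adjusted p = 8.43e-11), carboxypeptidase Cpa3 4.75 ± 0.13 (adjusted p = 3.34e-11) and histidine decarboxylase Hdc 4.16 ± 0.21 (adjusted p = 4.07e-09). Titin Ttn went from 711 to 145 CPM in WT and from 208 to 1046 ± 330 CPM in KO (4.58 ± 0.25, adjusted p = 6.89e-09), and 10 of 11 muscle genes had a positive interaction (median 2.66, adjusted p = 0.000165; 0.364 with an estimated correlation). Complement C3 was 190 and 188 CPM at 2 and 12 months in WT and 54.7 and 541 CPM in KO (3.31 ± 0.12, adjusted p = 2.09e-10). Cxcl2 had 3.95 ± 0.13 (adjusted p = 1.48e-10), the stromelysin Mmp3 2.00 ± 0.08, and the oligoadenylate synthetase Oas2 2.89 ± 0.17. In the NF-kB list 23 of 32 were positive and 5 negative (median 1.39, adjusted p = 6.46e-06; 0.182 with an estimated correlation), and in the endothelial list 13 of 15 were positive and 1 negative (median 1.52, adjusted p = 9.37e-06; 0.155 with an estimated correlation). Sterol synthesis genes were positive in 20 of 24 (median 0.64, adjusted p = 2.41e-06; 0.155 with an estimated correlation). Glycolysis genes were positive in 19 of 31 (20 adjusted over the list alone; median 0.45, adjusted p = 0.000805; 0.399 with an estimated correlation).

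Negative interactions were called for several luminal genes. Csn3 had -6.76 ± 0.16 (adjusted p = 2.14e-11), Arg1 -5.18 ± 0.16 (adjusted p = 8.43e-11), Krt18 -3.80 ± 0.11 (adjusted p = 8.43e-11) and Krt8 -3.73 ± 0.19 (adjusted p = 4.17e-09). Sox10, a neural crest factor also found in mammary progenitors, was 3.16 and 50.2 CPM at 2 and 12 months in WT and 4.06 and 3.69 CPM in KO (-3.95 ± 0.21, adjusted p = 6.37e-09). Epcam had -3.04 ± 0.12 and Cd24a -2.75. The luminal progenitor list had 18 of 23 negative and 3 positive (4 positive adjusted over the list alone), with a median of -1.48 (adjusted p = 2.4e-06; 0.155 with an estimated correlation). Respiratory chain genes were negative in 25 of 51 (median -0.31, adjusted p = 8.61e-05; 0.395 with an estimated correlation). The p53 target list was called with 19 of 37 negative (20 adjusted over the list alone) and 6 positive (median -0.35, adjusted p = 0.044; 0.364 with an estimated correlation), among them Perp (-2.70) and Pmaip1 (-1.32 ± 0.12). That p53 list call was lost with no trend and without replicate 3 of 2-month WT, replicate 1 or 2 of 12-month WT, replicate 2 of 2-month KO or replicate 2 of 12-month KO (adjusted p = 0.0517 to 0.0661). Other lists hold 9 of the p53 targets. The division lists did not pass, with an interaction median of -0.10 for G2/M (adjusted p = 0.352; -0.19 and 0.0414 without replicate 2 of 12-month KO, 0.06 and 0.755 without its replicate 3) and 0.10 for G1/S (adjusted p = 0.555).

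**Figure D5:**
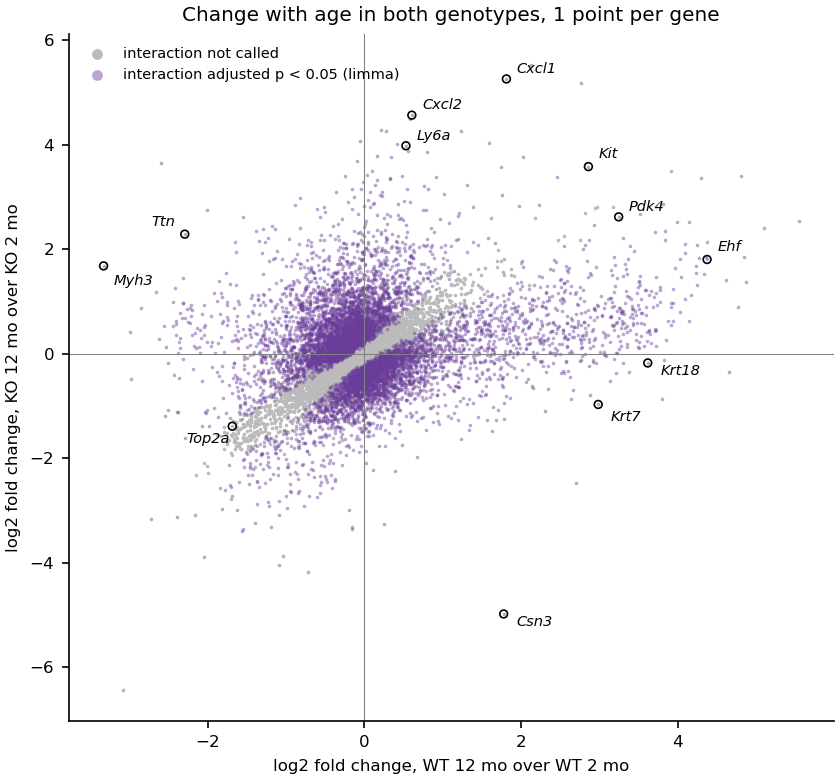
Log2 fold change with age in WT (x axis) and in KO (y axis), 1 point per gene, with genes at an interaction adjusted p under 0.05 in purple. Krt18 rose by 3.62 in WT alone, Cxcl1 rose by 5.26 in KO, and Kit rose in both (2.86 and 3.58).

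Across the 13961 genes, which are not independent replicates, 4 pairs of effects were correlated. The age effects in WT and KO, which share no library, correlated at r = 0.337 (Spearman rho 0.294), with the same sign in 59.84% of genes. Both rose in 1636 genes against 1026 for independent lists, and both fell in 2246 against 1698. Genotype effects at 2 and 12 months correlated at r = -0.0652 (rho -0.0273). The age effect in WT and the genotype effect at 12 months share the 12-month WT libraries and correlated at r = -0.611 (rho -0.481), where unchanged simulated groups gave -0.498. Their covariance was -0.393 against a simulated -0.0065, a difference of -0.387. Their signs were opposite in 65.49% of genes, against 66.71% in the simulation with nothing changed. That simulation holds noise alone, so its r and sign share do not measure how much the shared libraries added where many genes changed. By covariance, the spread between replicates gave -0.0065 of the -0.393, a small part. The age effect in KO and the genotype effect at 2 months share the 2-month KO libraries and correlated at r = -0.303 (rho -0.273), where the simulation gave -0.499, with a covariance of -0.0613 against -0.0065. The 3 shared libraries were not split, since a pair of groups with at least 2 each needs more, so part of these last relations may come from them.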

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

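All tests of explanations in this part were chosen after the result was seen, except the correction for transcript length and GC content and the split counts.

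The age effect differed between WT and KO by limma's interaction test in 8051 genes and in 17 of the 39 lists, which is why the results below were looked at again. In 1 of 100 assignments of the 12 libraries to 4 groups of 3, the real one included, were as many genes called. Assignments that mix the groups put the large age and genotype differences into the spread, and the median count of the others was 0. The test therefore cannot single out an interaction from these differences. Nor can it exclude chance differences between animals or cultures, since the labels do not state whether libraries came from separate ones. The highest other assignment called 6747 genes and kept 2 of the real groups whole, and others called 3445 and 2274. Why these called so many was not tested.

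List medians of the interaction were positive for skeletal muscle (2.66), interferon response (1.58), endothelial (1.52), NF-kB (1.39), AP-1 (0.95), EMT (0.81), fibroblast (0.70), sterol synthesis (0.64), glycolysis (0.45) and the senescence-associated secretory list (0.22). They were negative for luminal keratins and claudins (-2.85), luminal progenitor (-1.48), histones (-1.09, or -0.68 without replicate 1 of 2-month WT), hormone-sensing luminal (-0.58), ribosomal proteins (-0.45), p53 targets (-0.35) and the respiratory chain (-0.31). None of these 17 lists was called with an estimated correlation, where the lowest adjusted p was 0.155.

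Single genes with the largest positive interaction were Mcpt4 (6.24), Myh3 (5.01), Cpa3 (4.75), Ttn (4.58), Hdc (4.16), the chemoattractant Rarres2 (4.12), the neural adhesion gene Chl1 (4.08), Serpina3m (3.98), Cxcl2 (3.95) and Serpinb2 (3.91). Those with the largest negative interaction were Csn3 (-6.76), Arg1 (-5.18), Klhdc7a (-5.02), Ccdc129 (-4.68), Krt7 (-3.96), Sox10 (-3.95), Cited4 (-3.88), Krt18 (-3.80), Krt8 (-3.73) and Lad1 (-3.68). Of the study genes, Myc (0.97), Numb (-0.40) and, in the fit without a filter, Insc (-0.88) differed between the genotypes in their age effect.

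Genes near Shc1 that differ by genotype at both ages are the first pattern weighed. Within 10 Mb of Shc1, 10 of 236 genes (4.237%) differed by more than 1 log2 in the same direction at 2 and 12 months, against 20 of 13725 elsewhere (0.1457%), a Fisher exact odds ratio of 30.28 (p = 3.52e-11), or 18.18 (p = 3.45e-06, 6 of 232 near genes) without Rps3a1, Cd1d2, Lce3a and Lce3f, which have near-identical copies. Of 142 windows of 20 Mb, the window around Shc1 held the most, with 10, and the highest other held 2. Among the near genes, Ivl, Lce3a, Lce3f, Crct1 and S100a11 lay together between 92570899 and 93526288, all lower in KO. The Fisher test treats genes as independent, so its p-values overstate the evidence where such neighbours change together. An effect of the Shc1 mutation on its immediate neighbours was argued against, since 0% (0 of 10, exact 95% interval to 30.85%) lay within 1 Mb. A chromosome 3 segment that differs between the knockout and WT strains is a candidate explanation that the clustering fits, while a cell-type mixture stays open, since 20% (2 of 10, exact 95% interval 2.521% to 55.61%) were also called with age in WT by more than 1 log2.

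Higher luminal genes in 12-month than in 2-month WT are the second pattern. The scaling between libraries was argued against, since the list median was at least 3.358 log2 over 5 other scalings or count tests. A lower share of stromal cells raising every other cell type alike was weighed by list medians. Those of the luminal, endothelial, macrophage and muscle lists (3.30, 0.19, -0.25 and -2.38) spanned 5.684 log2. This argued only against fewer fibroblasts raising all of these cell types alike. Endothelial, macrophage and muscle cells can themselves be counted as stroma, so a lower share of stromal cells as a whole stays open. A larger share of luminal cells among 12-month WT mammosphere cells cannot be told apart from higher expression per luminal cell, since each library sums the RNA of all its cells. Of the luminal progenitor and hormone-sensing genes outside the keratin and claudin list, 64.29% (27 of 42) rose by more than 1 log2. That lay between the bounds set for and against a larger share, but no value of it could have separated these explanations. The difference in age itself stays open and was not tested apart from cell composition.

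Lower ribosomal protein and respiratory chain lists in 12-month than in 2-month KO are the third pattern, both made of short transcripts (median 1094 and 1232 bases against 3416 for all genes), with medians of -0.73 and -0.43 without replicate 3 of 12-month KO, which fell least. A trend of the fold change with transcript length and GC content was argued against as the whole cause, since at least 66.67% of each list median remained after it was removed (-0.58 to -0.48 and -0.39 to -0.26). These lengths are of the longest transcript per gene, so a trend with the lengths expressed may have been removed only in part. Fewer dividing cells were weighed against WT, which lost division genes alike (G2/M median -1.52 against -1.58 in KO) but showed at most 24.69% of the KO fall of these lists. With sample weights the ribosomal protein median in WT was -0.32 (adjusted p = 0.00768), against -0.14 in the main fit. This argued against fewer dividing cells only if no other age change in WT offset such a fall, and luminal genes rose there (median 3.30). A larger share of nuclear RNA cannot be told apart from a change in these transcripts. The median of 9 RNAs taken as nuclear-retained was 0.3935 with 6 of 9 higher, from Snhg11 (1.62) and Malat1 (1.41) to Meg3 (-2.32). Whether each of the 9, among them Gas5 (-0.24), stays in the nucleus was not checked, and the median depends on that choice. The difference in age itself also stays open.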

How the results depend on the processing

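TMM recomputed over all 12 libraries was chosen after the data were seen, and the other alternatives were planned.

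Of 781 named gene results, 731 kept their call and direction in every setting, 44 lost a call in at least 1 setting, 6 gained one and 1 reversed. The reversed gene, Rpl4 with age in WT, is also among the 44, at -0.18 (adjusted p = 0.00711) on the deposited scale and 0.0565 under quantile scaling (adjusted p = 0.422); the cause was not tested. Myc with age in WT lost its call in 11 settings and Trp53 in 8, and Mki67 by genotype at 12 months gained one in 8.

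Counts of changed genes stayed within 1.5 times the reported ones for both age comparisons, the 12-month genotype comparison and the interaction in every setting run. For genotype at 2 months, 2245 genes became 1415 with median-of-ratios scaling, 1322 with quantile scaling, 1426 with edgeR, 1454 with TMM recomputed over all 12 libraries and 6912 with sample weights, whose estimation stopped before its convergence tolerance; the cause was not tested. DESeq2 gave 1727. Leaving out 1 library at a time gave 7225 to 8161 genes for age in WT, 8546 to 9749 for age in KO, 1407 to 3033 for genotype at 2 months, 9062 to 10150 for genotype at 12 months and 7344 to 8273 for the interaction. The ends at 2 months came without replicate 1 of KO and without replicate 1 of WT, and 1493 genes were called without replicate 3 of KO.

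The number of called lists fell from 20 to 4 for age in WT with an estimated correlation, and from 21, 13, 17 and 17 to 0 in each other comparison. fry called 35 lists for age in KO, 25 for genotype at 2 months, 34 for genotype at 12 months and 30 for the interaction, since it tests a direction without comparing a list with other genes. It called the asymmetric division list in every comparison except age in KO (adjusted p = 2.07e-05 to 0.0424, the lowest for genotype at 12 months). Leaving out 1 library gave 18 to 21, 20 to 23, 11 to 14, 17 to 18 and 16 to 18 called lists in the 5 comparisons. At 2 months, the histone list had a median of -0.26 with sample weights (adjusted p = 0.717), and of -0.25 to 0.25 over the fits without 1 library, the lowest without replicate 1 of WT (adjusted p = 0.697). The fry test reversed the direction of the ribosome biogenesis list (median -0.0101, adjusted p = 0.479) and the AP-1 list (median -0.0219, adjusted p = 0.977) at 2 months. There, camera compared each list with the other genes, and the median of all genes was -0.0877, while fry compared it with no change. Over all settings together, those above included, 1945 results of the lists called in the main fit kept their direction and call. Another 146 lost their call in the same direction, and 4 reversed and lost it too. Calls gained by other lists are not in these counts. The Notch list with age in WT lost its call in 11 settings (adjusted p = 0.0504 to 0.183), and the p53 target list in the interaction in 7 (0.0517 to 0.364). At 2 months fry also lost the extracellular matrix (0.11), luminal keratin and claudin (0.0714) and unfolded protein response (0.354) lists. In the interaction, fry lost the histone list (0.0528) and quantile scaling the senescence-associated (0.127) and fibroblast (0.171) lists.

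Whether replicate numbers pair the libraries cannot be told. Same-number pairs had a median correlation of 0.09265 against -0.0558 for other pairs. Of 18 same-number pairs 8 correlated above 0.1 (range -0.163 to 0.589), and 6 of 12 libraries correlated best with their own number. With the replicate block 8453, 9681, 2590, 10079 and 8517 genes were called in the 5 comparisons, more than without it in each. No list gained or lost a call with the block.

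The correlation of age effects in WT and KO was 0.3205 to 0.3606 over the fits without 1 library, and the correlation of WT age effect with genotype effect at 12 months was -0.6283 to -0.5794. Depth limits Insc, which had 2, 9 and 14 reads in the 12-month KO libraries.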

Other observations

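The split counts in this part were planned, and the naming of mast-cell genes was chosen after their values were seen.

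Among genes known from mast cells, carboxypeptidase Cpa3 was 47.7 ± 5.94 CPM in 2-month WT, 11.5 ± 1.14 in 12-month WT, 10.97 ± 0.0784 in 2-month KO and 76.5 ± 3.72 in 12-month KO (n = 3 each). The chymases Mcpt4 and Cma1 were 4.65 and 30.9 CPM in 2-month WT, 0.346 and 12.3 in 12-month WT, 0.333 and 6.93 in 2-month KO, and 9.95 and 38.6 in 12-month KO. Outside the naming rule, tryptase Tpsb2 had an interaction of 2.97 ± 0.18 (adjusted p = 1.68e-08), the IgE receptor genes Fcer1a and Ms4a2 3.31 ± 0.19 (adjusted p = 1.03e-08) and 2.09 ± 0.21 (adjusted p = 1.56e-06). The receptor Kit, which mast cells share with luminal progenitors, rose with age in both genotypes, by 2.86 in WT and 3.58 in KO. No list of mast-cell genes had been fixed, so no source was tested.

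Muscle genes did not share 1 order of groups. Ttn was 711 ± 70.5 CPM in 2-month WT, 145 ± 10.4 in 12-month WT, 208 ± 30.3 in 2-month KO and 1046 ± 330 in 12-month KO, while Myh3 was 61.9, 5.69, 8.84 and 30.9 CPM in the same order. The macrophage list was not called with age in KO, with 14 of 23 genes lower and 5 higher (median -0.68, adjusted p = 0.0624). Its mean lay at -1.13 in replicate 2 of 12-month KO and at -0.46 and -0.44 in the others, relative to 2-month WT, and without replicate 2 the median change was -0.45 (adjusted p = 0.115). It was called without replicate 2 of 2-month KO or replicate 1 or 3 of 12-month KO (adjusted p = 0.0148 to 0.0407). No filter (adjusted p = 0.0232), a filter at a mean of 2 CPM (0.0183), median-of-ratios scaling (0.0458) and sample weights (0.0359) also called it. The myeloid gene Cd68 went from 60.3 ± 5.19 to 26.5 ± 6.86 CPM with age in KO.

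Lists not called with age in either genotype included apoptosis genes of the BCL2 family, with 7 of 28 higher and 8 lower in WT (adjusted p = 0.542) and 7 higher and 14 lower in KO (adjusted p = 0.335). The mammary stem-cell list had 12 of 27 genes higher and 7 lower in WT (adjusted p = 0.0726) and 13 higher and 7 lower in KO (adjusted p = 0.109). With no filter both were called (adjusted p = 0.0317 and 0.0376), and that in WT also without replicate 1 of 2-month WT (adjusted p = 0.042). Other lists hold 20 of its genes.

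Splits of the 6 libraries of each 2-group comparison into 3 and 3 number 10, too few for a share under 0.05. In each of the 4 comparisons 1 of 10 splits, the real one, called as many genes as the real 8091, 9358, 2245 and 9801, and the highest other split called 0 in limma.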
